A study of Mus musculus with 2 samples.

How the data were processed

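RNA of whole brains of C57BL/6J embryos at embryonic day 14.5 was measured in 2 libraries, per the labels stranded paired-end libraries of 101-nt reads from polyadenylated, rRNA-depleted RNA longer than 200 nt with spike-in RNA. Both libraries form 1 group and are numbered as biological replicates by the labels. The labels describe tissue of littermates, and which animals went into which library is not given in the sources used here, so the spread between the libraries may be technical.

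The deposited mm10 gene and transcript tables hold expected counts, which the authors estimated per gene and per transcript from alignments to the transcriptome with GENCODE M4, per the files' text notes; the tool is not given in the sources used here. The deposited TPM values are scaled over all genes with spike-in and mitochondrial entries included, and the deposited FPKM values are scaled by length and by assigned fragments. The deposited mm9 gene values are RPKM on Ensembl 65 annotation, with 2 values per gene whose replicate number is not tied to a sample. Every mm9 gene was listed on 2 lines, and 1 was kept, leaving 37310 of 74620 lines. Junction read counts, deposited by the authors with both replicates summed, came with a reproducibility value, a fraction for which low is reproducible. The deposited contigs carry a signal level whose scale is not given, and the same kind of reproducibility fraction. Exon positions of the deposited mm9 exon table were used only to derive annotated introns. Junctions tagged as annotated matched these introns in 100% of cases and the other junctions in 0%.

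Gene symbols, biotypes and mm10 coordinates came from GENCODE vM21, matched by Ensembl identifier; 884 of 43346 annotated genes had no symbol there and are not named. The 26248 rows with numbers for names held no counts. The 97 spike-in rows were kept out of library sizes and tests. Of 399 list members, 396 were matched. Values of some single genes are not reported here, although the counts of lists and pairs include them.

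Before the data were examined, 42 gene lists, 22 gene pairs and 25 isoform genes were fixed, with the rule for named genes: the 15 highest nuclear protein-coding genes, the 3 highest members of each list and any list member that differed 2-fold or more between the libraries, the 15 largest differences between the libraries at a mean of 100 expected counts and 5 TPM or more, and the members of pairs and isoform genes, of which the text names a part. Mki67, Xist, Krtdap, Sbsn, Sfn, Lor and Gm26917 fall outside that rule and were named after their values were seen. List levels were set against 10000 random lists of the same size, and differences between libraries, as log2(TPM + 1) ratios, against 10000 random lists matched on mean expression in 20 bins. A pair was called apart where both libraries gave the same sign and the mean log2 ratio exceeded 1 and its SD. Values with a pseudocount understate differences of low genes. The common biological coefficient of variation came from edgeR 4.0.16 with an intercept-only design on expected counts rounded to whole numbers, TMM normalization and a summed count of 10 or more. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, R 4.3.3, DESeq2 1.42.0 and bedtools 2.31.1 were used.

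The steps were tested on simulated data. With a true coefficient of variation of 0.2 and 200 genes changed, edgeR estimated 0.222 over 20182 genes and the median fold of genes raised 4-fold was 4.02. Of 200 random lists of unchanged genes 5% were called, and of 200 lists of raised genes 100%, over 18943 genes. Genes were simulated independently, so the 5% does not cover lists whose members vary together.

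At these depths 3 counts correspond to 2.78e-06% of the counts in replicate 1 and 2.97e-06% in replicate 2. These floors cover counting error only. Alternatives covered the TPM threshold, posterior mean TPM, rescaling without mitochondrial and spike-in rows, FPKM, the pseudocount, DESeq2 size factors, low-count filters, each library left out, mm9 values, transcript filters, and junction and contig thresholds. A correction for transcript length and GC content (a polynomial of degree 3), the hindbrain minus forebrain difference, rescaling without Gm42418 and 4 added gene lists were chosen after the data were seen. Standard errors of medians came from 2000 bootstrap draws of list members. They treat members as independent, although members can vary together, and do not measure the error between libraries. A list was run with that correction only where 80% or more of its fixed members had a corrected value, which left out 12 of 42 lists, among them 5 that lay outside random lists without it: the posterior Hox, astrocyte, erythroid, imprinted and mitochondrial mRNA lists. The mm9 exon and transcript values and de novo exon and transcript models were not used here.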

Results

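Polyadenylated RNA of the whole brain of C57BL/6J mouse embryos at embryonic day 14.5 was sequenced in 2 libraries, which the labels number as biological replicates 1 and 2 and describe as coming from littermates of both sexes. Both libraries belong to the same group, so no contrast between conditions exists. The questions addressed were which genes and transcripts this tissue expressed, at what level, and how far the 2 samples differed. The expected counts summed to 107938353 in replicate 1 and 101105391 in replicate 2, of which 103493289 and 97539730 fell on annotated genes. The spread between the libraries was the only error available, and no p-value per gene was computed, since 1 library against 1 leaves no residual degrees of freedom.

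Of 43346 annotated genes, 14694 reached a TPM of 1 or more in both libraries, among them 13349 of 21474 protein-coding genes. Tubulins led the nuclear protein-coding genes. Tuba1a, an alpha-tubulin of growing neurons on chromosome 15 (98949837 to 98953703 in mm10), stood at 11335 ± 1325 TPM (SD, n = 2), Tubb2b at 7300 ± 966 TPM (SD, n = 2) and the neuronal beta-tubulin Tubb3 at 2696 ± 79.8 TPM (SD, n = 2). Tubb2a at 2826 ± 437 TPM (SD, n = 2) and Tubb5 at 2750 ± 284 TPM (SD, n = 2) were also among the 15 highest. These tubulins share sequence with one another, so the division of reads between them is uncertain. The imprinted gene Nnat reached 7146 ± 1425 TPM (SD, n = 2). Adult globins of circulating red cells were in the same set, with Hba-a2 at 4576 ± 891 TPM (SD, n = 2) and Hbb-bs at 2909 ± 5.68 TPM (SD, n = 2). Both have near-identical copies, Hba-a1 and Hbb-bt, so their values are uncertain. The other 7 of the 15 were Eef1a1, Rplp1, Ubb, Actb, Rps12, Gapdh and Hspa8, at 2405 to 5933 TPM. Mitochondrial genes took 8.49% of the TPM in replicate 1 and 12.2% in replicate 2, against 1.61% and 2.28% of the expected counts, and mt-Atp8, a short transcript, was listed at 53458 and 77705 TPM.

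Genes of young neurons were the most abundant of the brain cell lists. All 17 members reached 1 TPM in both libraries, and their median TPM was 253 in replicate 1 and 379 in replicate 2. Dpysl3, which encodes a growth cone protein, stood at 712 ± 111 TPM (SD, n = 2) and the growth cone gene Gap43 at 701 ± 223 TPM (SD, n = 2). All 13 radial glia and neural stem cell genes were detected, with medians of 63.2 and 57.8 TPM, led by the intermediate filament gene Vim at 900 ± 158 TPM (SD, n = 2) and the lipid-binding gene Fabp7 at 814 ± 68.5 TPM (SD, n = 2). All 15 cell cycle genes, 8 intermediate progenitor genes, 12 excitatory and 12 inhibitory neuron genes were detected. The median of the mean TPM was 47.2 for cell cycle genes, 41.0 for intermediate progenitors, 32.5 for excitatory and 46.8 for inhibitory neuron genes. Of the 12 mature synapse genes 11 were detected, with a median of 29.1 TPM. By the mean of the 2 libraries, each of these lists lay above the central 95% of random lists of protein-coding genes of the same size. Single libraries fell below that bound in 3 cases: intermediate progenitor genes in replicate 2 (31.8 TPM, bound 38.7), excitatory neuron genes in replicate 2 (22.1 TPM, bound 29.2) and mature synapse genes in replicate 1 (22.4 TPM, bound 29.0). Cajal-Retzius genes had a median of 34.0 TPM (percentile 92.4), with 5 of 5 detected, led by Reln at 83.2 ± 4.31 TPM (SD, n = 2).

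Glial, immune and transmitter-specific lists lay within the range of random lists. Myelin genes had a median of 7.46 TPM (percentile 51.5), with 4 of 6 detected. Oligodendrocyte precursor genes had a median of 8.70 TPM (percentile 56.5), with 6 of 6 detected. Microglia and macrophage genes had a median of 4.45 TPM (percentile 39.2), and the complement gene C1qb stood at 23.1 ± 3.08 TPM (SD, n = 2). Endothelial genes had a median of 15.9 TPM (percentile 81.4), led by the tight junction gene Cldn5 at 94.1 ± 2.18 TPM (SD, n = 2). Astrocyte genes had a median of 21.1 TPM (percentile 89.2), with 6 of 9 detected. Monoamine and acetylcholine neuron genes had a median of 2.92 TPM (percentile 29.1; 1.79 and 4.30 TPM in replicates 1 and 2), with 9 of 12 detected. Among regional lists, forebrain patterning genes had a median of 17.8 TPM, hindbrain Hox and segment genes 8.53 TPM, midbrain and cerebellum genes 5.97 TPM, and neural crest and sensory ganglion genes 5.33 TPM. The last 3 rested on unequal libraries: the medians in replicates 1 and 2 were 2.76 and 14.1 TPM for hindbrain genes, 1.65 and 8.70 TPM for midbrain and cerebellum genes, and 2.5 and 7.57 TPM for neural crest genes.

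Markers of blood and of tissues around the brain were present at unequal levels. Erythroid genes had a median of 40.9 TPM, with 9 of 11 measured members detected, and meningeal and fibroblast genes had a median of 47.2 TPM, with 8 of 8 detected. Choroid plexus genes had a median of 16.7 TPM, and Ttr, which encodes the thyroid hormone carrier transthyretin, reached 1165 ± 242 TPM (SD, n = 2). Pericyte and smooth muscle genes had a median of 12.2 TPM, with 7 of 8 detected. Keratin genes of the skin list had a median of 10.5 TPM with 5 of 5 detected. Pituitary, lens and posterior Hox lists were the 3 of 42 lists with a median below 1 TPM, at 0.0175, 0.16 and 0.0425 TPM. The pituitary median was 0 TPM in each library, and the posterior Hox median was 0.08 TPM in replicate 1 and 0.025 TPM in replicate 2. With mm9 values, in a different unit, 27 of 42 lists had a median RPKM of 1 or more. None of the 10 posterior Hox genes reached 1 TPM in both libraries. Skeletal muscle (1.01 TPM), cartilage (1.17 TPM) and liver (1.68 TPM) lists lay just above that level, and the skeletal muscle median was 0.785 TPM without replicate 2.

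Imprinted genes and long noncoding RNAs stood far above random lists, at medians of 262 and 454 TPM, the latter from 271 TPM in replicate 1 and 496 TPM in replicate 2. Meg3, a maternally expressed noncoding RNA, was at 3164 ± 955 TPM (SD, n = 2), Rian at 2318 ± 448 TPM (SD, n = 2) and Miat at 778 ± 96.0 TPM (SD, n = 2). Neuronal splicing regulators had a median of 77.6 TPM with 12 of 12 detected, and axon guidance genes a median of 41.9 TPM with 12 of 12 detected. Microcephaly genes had a median of 4.86 TPM (percentile 45.1), although all 9 were detected. Notch and Shh pathway genes had a median of 13.3 TPM (percentile 78.0). Ribosomal protein genes (872 TPM) and housekeeping genes (248 TPM) lay above random lists (percentile 100), while hypoxia genes (12.7 TPM), replication-dependent histones (11.2 TPM), Y-linked genes (10.3 TPM) and immediate early and heat shock genes (5.22 TPM) lay within their range. Histone genes share sequence with copies, so their values are uncertain.

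Of the fixed gene pairs, those of cell cycle kinases, alpha globins and NMDA receptor subunits stood furthest apart. The NMDA receptor subunit Grin2b exceeded Grin2a by 4.10 ± 0.30 on the log2 scale (SD, n = 2; 2.96 with a pseudocount of 1). The neuronal BAF subunit Actl6b exceeded its progenitor counterpart Actl6a by 2.37 ± 0.12 (SD, n = 2), and Sox11 exceeded Sox2 by 1.40 ± 0.29 (SD, n = 2). The chloride importer Slc12a2 lay below the exporter Slc12a5, at -2.17 ± 0.20 (SD, n = 2). Cdk4 exceeded Cdk6 by 7.79 ± 0.43 (SD, n = 2), and Dnmt3a exceeded Dnmt3b by 3.17 ± 0.54 (SD, n = 2; 3.77 with mm9 RPKM). Among globins, the embryonic Hbb-y lay below the adult Hbb-bt at -1.91 ± 0.24 (SD, n = 2; -3.71 with mm9 RPKM), and Hba-a1 exceeded the embryonic Hba-x by 5.56 ± 0.23 (SD, n = 2; 7.61 with mm9 RPKM). Hbb-bt and Hba-a1 have near-identical copies, Hbb-bs and Hba-a2, so both globin ratios are uncertain. The copy Hbb-bs was higher than Hbb-bt, at 2909 against 1234 TPM, and is not part of the ratio. In all, 16 of 22 pairs were apart by more than 1 log2 unit and by more than their SD, 14 with the first gene higher. Slc17a6 over Slc17a7, the pair of vesicular glutamate transporters, did not hold up against the replicate spread: the log2 ratio was 0.40 in replicate 1 and 3.05 in replicate 2, and the pair counted as apart without replicate 1 and with mm9 RPKM (1.87). Ccnd2 over Ccnd1 counted as apart without replicate 2, at 1.14. The splicing regulators Ptbp2 and Ptbp1 were also not apart, at -0.19 ± 0.11 (SD, n = 2).

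**Figure D1:**
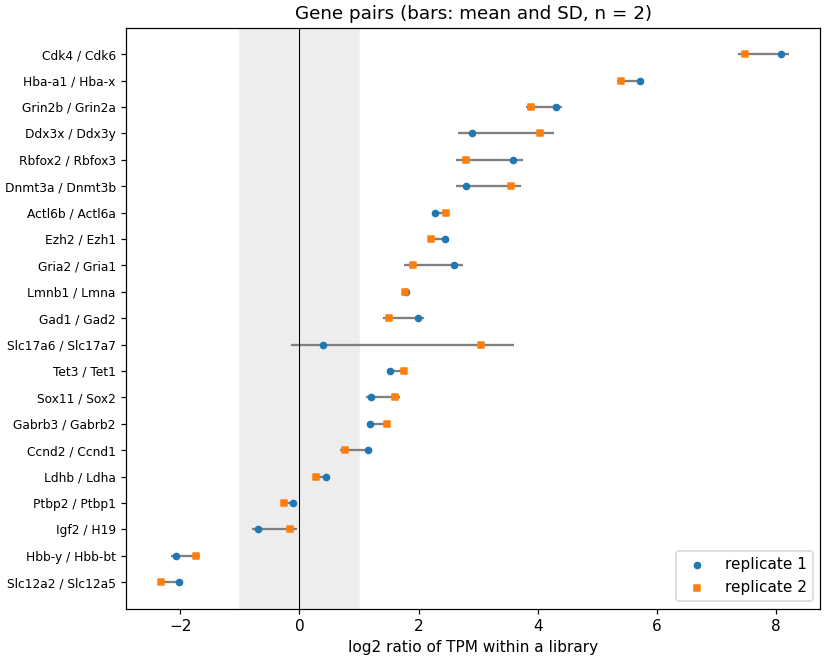
Log2 ratio of TPM of the first over the second gene of the fixed pairs, except 1 that is not reported here. Points are the 2 libraries, bars are the mean and SD (n = 2) and the shaded band marks 1 log2 unit on either side of 0; Cdk4 over Cdk6 is the highest at 7.79 and Slc12a2 over Slc12a5 the lowest at -2.17.

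Transcript shares of neuronal genes were close in the 2 libraries for most genes named. Mapt-204 took 97.3 ± 0.00886% of the summed TPM of the tau gene Mapt (SD, n = 2). Snap25-201 took 87.5 ± 1.67% of the synaptic gene Snap25 (SD, n = 2), and the other coding transcript took 12.1 ± 1.72% (SD, n = 2). Dcx-201 took 89.7 ± 1.51% of the doublecortin gene (SD, n = 2), and the pair of transcripts of Cdc42 took 50.6 ± 0.0788% and 49.4 ± 0.0788% (SD, n = 2). The leading transcript of the pyruvate kinase gene Pkm differed: Pkm-201 took 60.7% in replicate 1 and 48.3% in replicate 2. The leading transcript of Ncam1 also differed, and 1 of its transcripts took 42.9% and 46.9%. For Agrn the leading transcript, at 46.5 ± 0.806% (SD, n = 2), was one annotated as a retained intron. Over 6878 genes at 10 TPM or more with 2 or more transcripts, the leading transcript differed between the libraries in 558 (8.11%), and it held 50% or more in both libraries in 4619. With genes at 1 TPM or more, 916 genes differed. Transcripts named here overlap in sequence, so their shares are estimates.

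The 2 libraries differed along the head-to-tail axis of the brain. All 11 hindbrain Hox and segment genes were higher in replicate 2, by a median of 1.92 on the log2(TPM + 1) scale (percentile 100), 10 of them at least 2-fold. Hoxb3 was at 3.82 and 31.8 TPM in replicates 1 and 2, Hoxa5 at 4.10 and 35.8 TPM and Hoxb5 at 2.76 and 33.4 TPM. Midbrain and cerebellum patterning genes were higher by a median of 0.77 (10 of 11 members), with Pax2 at 1.59 and 15.4 TPM. All 8 forebrain patterning genes were lower in replicate 2, by a median log2 ratio of -0.37 (percentile 0.67; -0.59 with a pseudocount of 0.1), with Lhx2 at 227 and 122 TPM and Nkx2-1 at 62.8 and 22.4 TPM.

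Summed over paralog groups, Hox genes of group 2 were at 5.68 TPM in replicate 1 and 25.1 TPM in replicate 2, a log2 ratio of 2.14. Group 4 was at 3.80 and 31.95 TPM (3.07), and group 6 at 0.74 and 14.2 TPM (4.26). Groups 9 to 13 summed to at most 0.34 TPM each in both libraries. Hoxb8 rested on 19 expected counts in replicate 1 and 1249 in replicate 2.

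**Figure D2:**
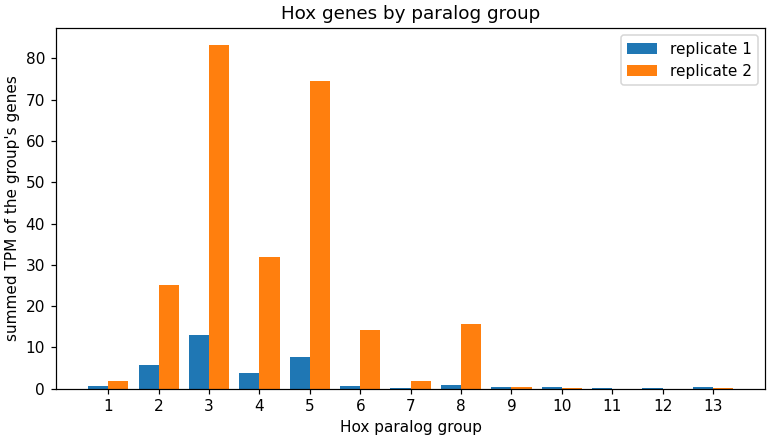
Summed TPM of the Hox genes of each paralog group (1 to 13) in each of the 2 libraries; bars start at 0. Groups 3 and 5 reached 83.3 and 74.5 TPM in replicate 2 against 13.1 and 7.69 TPM in replicate 1.

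Neuron and progenitor lists differed between the same libraries. Intermediate progenitor genes were lower in replicate 2 for 8 of 8 members, by a median log2 ratio of -0.996 (percentile 0), with Eomes at 27.96 and 9.62 TPM and Neurog2 at 82.1 and 35.0 TPM. Cell cycle genes were lower for 14 of 15 members, by a median of -0.83 (percentile 0), with Cdk1 at 167 and 70.7 TPM. The proliferation marker Mki67 was the exception, at 12.4 and 13.8 TPM. Excitatory neuron genes were lower for 11 of 12 members, by a median of -0.95 (percentile 0). The cortical genes Emx1, at 57.4 and 10.6 TPM, and Fezf2, at 59.0 and 11.4 TPM, were among them. Inhibitory neuron genes were lower by a median of -0.51 (9 of 12 members), with Dlx1 at 220 and 71.2 TPM, while the glycine transporter gene Slc6a5 was higher at 1.77 and 7.65 TPM. Neural crest and sensory ganglion genes were higher for 7 of 8 members, by a median of 0.92 (percentile 100). Young neuron genes were higher for 15 of 17 members, by a median of 0.32 (percentile 100), and radial glia genes lay inside the range of random lists at -0.24 (percentile 13.4). The astrocyte (0.57, 7 of 9 members higher) and oligodendrocyte precursor (0.56, 5 of 6) medians were higher. So were the monoamine and acetylcholine (0.55, 9 of 12) and axon guidance (0.50, 8 of 12) medians. The 3 lower monoamine and acetylcholine genes were the highest of that list. They were Isl1 (59.8 and 37.05 TPM), Slc18a2 (29.1 and 18.4 TPM) and Th (14.85 and 11.3 TPM). Cxcr4 and Efnb2 were among the 4 lower axon guidance genes. The microcephaly median was lower (-0.33). The mature synapse (0.31), neuronal splicing (0.14) and imprinted (0.06) medians lay above random lists. After a trend with transcript length and GC content was removed, the mature synapse (0.14) and neuronal splicing (0.02) medians lay inside that range, and the medians of inhibitory neuron (-0.25), axon guidance (0.26), endothelial (0.29), microcephaly (-0.59) and choroid plexus (0.66) genes shifted by over 1.5 times but stayed outside it. The imprinted list lay within random lists with a pseudocount of 0.1, and its median was 0.12 after rescaling without mitochondrial and spike-in rows.

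Ribosomal, mitochondrial and non-neural transcripts differed as well. Gm42418, a noncoding transcript annotated over rRNA-like sequence on chromosome 17 (39846958 to 39848788 in mm10), was at 2142 TPM in replicate 1 and 20469 TPM in replicate 2, and mt-Rnr2 at 303 and 2617 TPM. Mitochondrially encoded mRNAs were higher for 13 of 13 members, by a median of 0.45. The bone matrix gene Ibsp was at 0.17 and 20.3 TPM, and Col1a1 at 36.5 and 146 TPM. Erythroid (0.42, 11 of 11 members higher) and choroid plexus (0.43, 7 of 7) medians were higher in replicate 2. So were the meningeal (0.35, 7 of 8) and endothelial (0.47, 6 of 9) medians. The 3 highest endothelial genes, Cldn5, Slc2a1 and Esam, were nearly level, at log2 ratios of -0.05, -0.07 and -0.03. Microglia genes lay inside the range of random lists (-0.02). The 4 Y-linked genes were lower by a median of -0.53 (percentile 0.41), and Xist, the noncoding RNA of the inactive X chromosome, was at 112 and 146 TPM. Srp54a, at 0.27 and 15.1 TPM, has near-identical copies, and Gm10335 and Gm10132 are processed pseudogenes; their values are uncertain. The 15 genes with the largest differences were all higher in replicate 2, and also held Hoxa3 at 1.34 and 15.5 TPM, Hoxb6 at 0.57 and 10.9 TPM, Gm38182 at 3.69 and 28.4 TPM and mt-Rnr1 at 148 and 928 TPM.

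**Figure D3:**
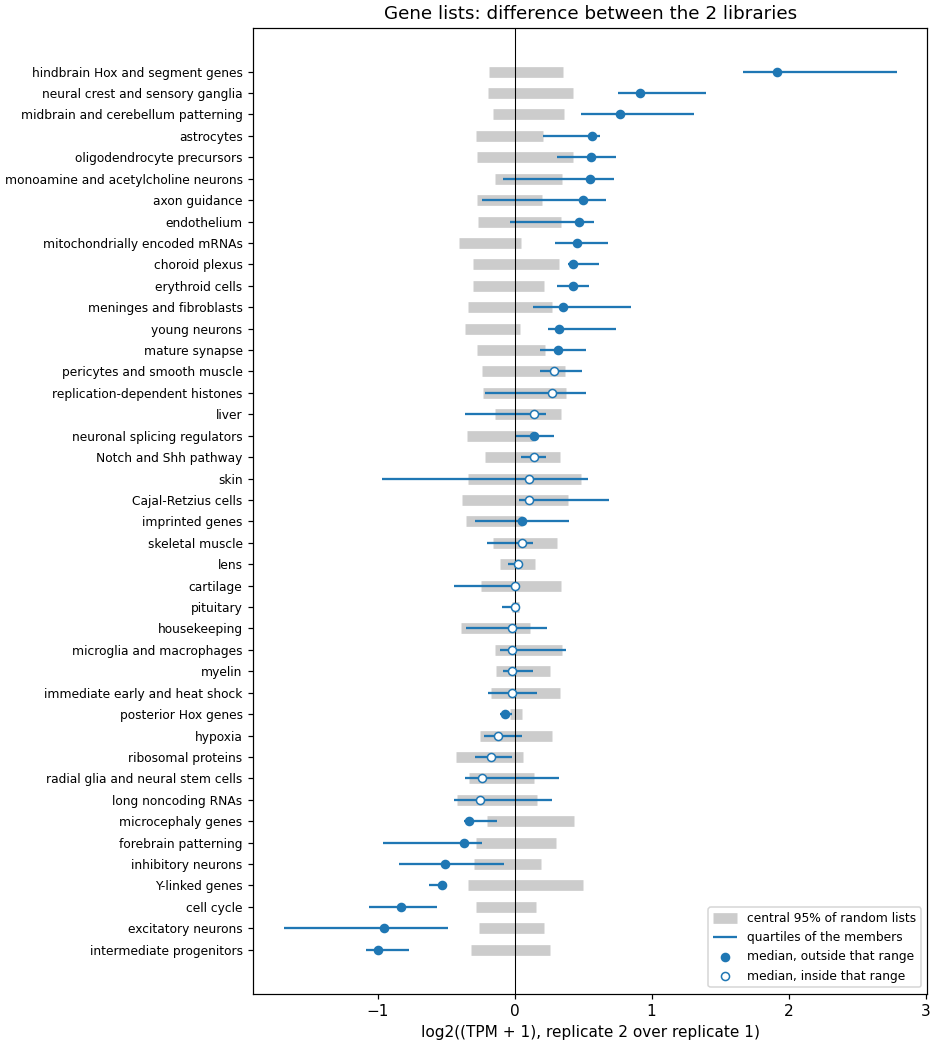
Median log2((TPM + 1) ratio, replicate 2 over replicate 1) of each of the 42 fixed lists, with the quartiles of its members (line) and the central 95% of 10000 random lists matched on expression (grey bar). Filled points lie outside that range; the hindbrain list is the highest at 1.92 and the intermediate progenitor list the lowest at -0.996.

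In all, 24 of 42 lists lay outside the central 95% of random lists matched on expression, 16 higher and 8 lower in replicate 2. For lists of unrelated genes 2.1 would be expected. Members of the fixed lists can vary together and some lists share members, so 2.1 is no measure of chance here. The posterior Hox list counted among the 8 at -0.07 (-0.40 with a pseudocount of 0.1), with its genes close to 0 TPM. The liver list lay outside with members at 1 TPM or more only (-0.52, against 0.14 over all members), and the histone list after the trend with length and GC content was removed (0.42). These lists describe the 2 libraries and carry no test between conditions. The common biological coefficient of variation estimated by edgeR was 0.264 over 20211 genes, and the median absolute log2 ratio was 0.27 over 15240 genes at a mean of 1 TPM or more, of which 364 were at least 2-fold higher and 173 at least 2-fold lower in replicate 2. A chi-square test of the 2 libraries' counts gave 279 per degree of freedom over 20211 genes, above the sampling noise of 1 library deposited in 2 parts, so the libraries were counted as 2 samples. The test does not tell biological from technical replicates. The log2 ratio was correlated with transcript length across 13629 genes, which are not independent replicates (Spearman rho = 0.457).

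The mm9 values deposited by the authors gave a rank order of genes close to that of the mm10 values. Across 33068 genes matched by Ensembl identifier, the mean mm9 RPKM and the mean mm10 TPM had a Spearman rho of 0.950; genes are not independent replicates. Of 13984 matched genes at 1 TPM or more in both libraries, 9528 (68.1%) also had an RPKM of 1 or more in both mm9 values, 2 units on different scales. Of 1213972 deposited splice junctions, 220122 had a reproducibility value of 0.1 or less and 2 or more reads. Annotated introns of Ensembl 65 accounted for 74.0% of these junctions and 96.4% of their reads, and the remaining 57143 junctions had a median of 13 reads against 207. Of 424626 contigs at a reproducibility value of 0.1 or less, 74.0% overlapped an annotated gene on the same strand, and these held 86.0% of the covered length.

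Spike-in RNA took 4.15 ± 0.26% of the TPM (SD, n = 2) and 3.82 ± 0.418% of the expected counts (SD, n = 2). By expected counts the share was 4.12% in replicate 1 and 3.53% in replicate 2. The phage phiX174, listed among these rows, took 2.29% and 1.46%, and without it the share was 1.83% and 2.06%, so the order of the libraries turned.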

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

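The tests of the 3 patterns below were chosen after the patterns were seen, and of these tests only the one on further brainstem and telencephalic genes was written down before the values it measures were looked at.

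Reads of the phage phiX174, listed among the spike-in rows, came to 2470239 expected counts in replicate 1 and 1479460 in replicate 2, in rows left out of the gene comparisons, of which the report gives only the share. Of the 159239 de novo gene models on mm9, 215 lay outside annotated genes on the same strand and had an RPKM of 1 or more in both values. The highest of these, on chromosome 11 (108872954 to 108873498 in mm9), had RPKM values of 307 and 915.

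Hindbrain genes were higher and forebrain genes lower in replicate 2, with a difference of medians of 2.29 on the log2 scale, and of 1.38 in size from mm9 RPKM. After the trend with length and GC content was removed the difference was 2.45 (bootstrap SE 0.449), which argues against that trend as the whole cause. Hindbrain genes exceeded vascular, blood and microglia genes by 1.58 (SE 0.367). Those cells lie in the forebrain too, so this value cannot test a smaller share of forebrain alone. Brainstem and spinal cord genes not in the fixed lists exceeded telencephalic genes not in them by 1.14 (SE 0.190; medians 0.83 over 11 genes and -0.31 over 11 genes), and more caudal tissue in the replicate 2 sample is a candidate explanation. A smaller share of forebrain would give that order as well, so that difference does not tell the explanations apart. On its own, a smaller share would raise genes silent in the forebrain by 1 common factor. Hindbrain genes rose by a median of 1.92 (quartiles 1.66 to 2.79), midbrain and cerebellum genes by 0.77 (0.48 to 1.31). Summed Hox groups 2, 3, 4 and 5 rose by 2.14, 2.67, 3.07 and 3.28. These unequal rises argue against a smaller forebrain share alone for these genes, if they are silent in the forebrain, which was not measured. Both libraries belong to 1 group, so no biological difference between groups was tested here or for the patterns below.

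rRNA-like transcripts were higher in replicate 2. The log2 ratios of the mitochondrial rRNAs exceeded that of the median mitochondrial mRNA by a mean of 2.43 (SD of the 13 mRNAs 0.244), which argues against more mitochondrial RNA of all kinds as the whole cause. The log2 ratios of Gm42418 and both mitochondrial rRNAs exceeded it by at least 2.20, and that of Gm26917, which lies beside Gm42418, by 1.48. The first 3 were picked for their large differences, so these values do not test carry-over of ribosomal RNA, which stays open.

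Cell cycle genes were lower in replicate 2, with Mki67 as the exception at 0.14. Their median was -0.83 before and after the trend with length and GC content was removed (SE 0.0971), when Mki67 was at -0.25, which argues against that trend as the whole cause. Radial glia genes lay above the cell cycle genes by 0.59 (SE 0.236), within 2 SE of the bound of 0.25, so fewer progenitors of every kind stays open.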

How the results depend on the processing

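The correction for length and GC content, the rescaling without Gm42418 and the hindbrain minus forebrain difference with its alternatives were chosen after the data were seen. Of 340 recomputed values none turned the direction of a called result. Of single lists, pairs and genes 289 kept their call, 3 lost it and 7 gained it. The count of detected genes ran from 11216 at 5 TPM to 19049 at 0.1 TPM, the lists at a median of 1 or more from 27 of 42 with mm9 RPKM to 39 with TPM, and the pairs apart from 16 to 18 of 22. Against 24 of 42 lists, 23 of 42 lay outside random lists with a pseudocount of 0.1, 23 of 41 after rescaling, 24 of 39 with members at 1 TPM or more, and 18 of 30 after the length and GC correction, where 19 of the same 30 lay outside without it. Without the low-count filter the coefficient of variation was 0.265. The median absolute log2 ratio was 0.256 with FPKM, 0.274 after rescaling and 0.298 with a pseudocount of 0.1. Hindbrain minus forebrain was 1.38 in size from mm9 RPKM. Leading transcripts differed in 916 genes at 1 TPM, the spike-in share was 3.82% of expected counts, and the mm9 rho was 0.928 among genes at 1 TPM or more. Without a reproducibility threshold there were 486558 junctions, and 56.2% of contigs overlapped genes. That share was 73.1% with an overlap of 50% of the contig and 80.3% on either strand. The cause of these shifts was not tested. The mature synapse and neuronal splicing lists no longer lay outside random lists after the length and GC correction, at 0.14 and 0.02. That correction is void for 12 lists in which under 80% of the members had a corrected value. Apart from the size of hindbrain minus forebrain, list differences from mm9 values were not run, since those values are not tied to the libraries. With 2 libraries, depth limits low genes such as Hoxb8, with 19 expected counts in replicate 1.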

Other observations

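The tests on bone and epidermis genes were written down before the values of the genes in them were looked at, after other bone and skin genes had been seen to differ. The values expected at the folds of Krt10 and Krtdap, and the look at members at 1 TPM or more, were added after the epidermis value was seen.

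Single genes of bone and epidermis differed between the libraries, while the skin, skeletal muscle, cartilage and liver lists, over all members, lay inside the range of random lists. Ibsp, a bone matrix gene, rested on 21 expected counts in replicate 1 and 2308 in replicate 2, and the epidermal gene Krtdap was at 25.5 and 4.22 TPM. Krt10, of differentiated epidermis, was at 13.5 and 5.26 TPM, while the basal keratins Krt5 and Krt14 were at 25.5 and 37.8 TPM and at 18.9 and 27.9 TPM. Pericyte (0.28), histone (0.27), Notch and Shh (0.14), liver (0.14), skin (0.11), Cajal-Retzius (0.10), skeletal muscle (0.05) and lens (0.03) medians lay inside the range of random lists, as did those of noncoding RNA (-0.25), ribosomal protein (-0.17) and hypoxia (-0.12) genes. Cartilage and pituitary medians were 0, and myelin, housekeeping and immediate early medians were -0.02.

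The presence of bone tissue in the replicate 2 sample was tested as a hypothesis on 8 bone genes not seen before. Their median log2 ratio was 0.57 (bootstrap SE 0.279), with 7 of 8 higher in replicate 2. It lay above random lists (percentile 99.99) but within 2 SE of the bound of 0.5, so the hypothesis stays open. Of the 8 genes, 1 reached 1 TPM in both libraries. Bone in the replicate 2 sample alone would also leave these genes low in replicate 1, so that count does not weigh against the hypothesis.

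More epidermis in the replicate 1 sample was tested on 7 further epidermis genes, whose median log2 ratio was -0.014 (SE 0.0924, percentile 9.85). The bound written for this test, a median above -0.5, was met by more than 2 SE, which argues against more epidermis as the whole cause of the lower Krtdap and Krt10. The list is low, at a median of 0.545 TPM, and a requirement of 1 TPM, tried after the value was seen and not kept, would have left the explanation open. With every member at the fold of Krtdap the median would have been -0.74, and at that of Krt10 -0.45, which does not reach the bound; the observed value lay above both by more than 2 SE. The 3 members at 1 TPM or more in both libraries were Sbsn at 30.3 and 29.3 TPM, Sfn at 8.31 and 9.03 TPM and Lor at 4.77 and 5.77 TPM, at log2 ratios of -0.05 to 0.23, and a change in the cells that express Krtdap and Krt10 stays open.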
